A study of Mus musculus with 30 samples.

How the data were processed

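RNA was measured by RNA-seq in growing C2C12 myoblasts sorted into G1, S and G2/M fractions, with 2 columns of values per phase. The values are deposited counts of fragments per gene, made with featureCounts 1.5.0-p3 from paired reads over exons grouped by gene in an Ensembl GRCm38 annotation, per the file headers. The command in the header names no option for strand, multiply mapping reads or overlapping genes, so fragments of overlapping antisense genes cannot be told apart, and genes with near-identical copies are uncertain. Reads had 101 cycles, per the labels' protocols. HISAT2 2.1.0, SAMtools 1.6, featureCounts 1.5.0, R 4.0.1, Bowtie2 2.3.0 and deepTools 3.5.0 are named per the submitters' processing notes, with no role given there. Any trimming or filtering of reads is not given in the sources used here. The 24 ChIP-seq samples are not analysed here.

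Gene identifiers were matched to symbols in a supplied table for 45143 of 46078 genes (98.0%), and positions are those the deposited table gives. The 6 columns were matched to samples by the names their descriptions give. Before any comparison the 2 columns of each phase were compared, because the sample titles number them as replicates while their file labels could stand for lanes of 1 library. Over genes with at least 10 fragments in the pair, chi-square against equal expression was 11297.1 over 11279 degrees of freedom in G1 (p = 0.450), 12090.1 over 11736 in S (p = 0.0109) and 13006.9 over 11281 in G2/M (p = 3.11e-28, and 0.00229 without the gene model Gm17082). These p-values compare the reads of 2 columns, not conditions. Strictly, G1 alone met the planned criterion of no difference. S and G2/M exceeded it by so little that the pairs were still treated as repeat measurements of 1 library. Across all 6 columns edgeR's common biological coefficient of variation was 0.988%, the lower limit of its estimate, which it also gave for columns simulated with 0 variation. In simulated columns with a variation of 0, 5, 10 and 20%, chi-square over its degrees of freedom was 1.00, 4.62, 14.2 and 53.3. Treating the columns as replicates would call 84.7% of 12489 genes between S and G1, 83.6% between G2/M and S and 84.8% between G2/M and G1 at an FDR of 0.05 with edgeR's quasi-likelihood test, which compares these libraries only. That planned fit was therefore replaced by the fallback written with it: counts summed to 1 library per phase, no p-values across genes, and genes named by the size of their ratio.

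Summed counts were scaled to CPM with TMM factors from edgeR 4.0.16 in R 4.3.3 (limma 3.58.1 loaded), over 12244 genes. The factors were 0.989 for G1, 1.00 for S and 1.01 for G2/M. A log2 ratio was taken after a gene with fewer than 3 fragments in a library was set to 3, and a ratio against a count of 0 is given as a lower bound. This bound takes the count in the other library as it is, and the exact interval can reach lower, for Arhgef39 to a log2 ratio of 7.04 against 7.34. A gene was counted as higher or lower at 2-fold or more, with at least 10 CPM in 1 of the 2 phases. Each ratio has an exact 95% interval from the binomial split of its fragments, and levels have exact Poisson intervals. As a scale for single genes, the percent of the 500 genes of nearest mean level with a smaller deviation was computed, and the robust SD of those genes. PCR copies are not independent molecules, so intervals and floors leave out all error but that of counting.

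Before the data were examined, 19 gene lists, the planned tests, the fallback, the rule for named genes and the main alternatives were fixed. The lists cover G1/S transition and DNA synthesis, G2/M and mitosis, origin licensing, replication-dependent histones, histone variants and chaperones, cyclins with their kinases and inhibitors, myogenic regulators, sarcomere genes, immediate early genes, H3K4 and H3K27 modifiers, heat shock, p53 targets, cholesterol synthesis, extracellular matrix, Notch, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear-retained and ribosomal RNA, and markers of other cell types. A list's median log2 ratio over members at 10 CPM in 1 of the phases was placed among 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean level. Members of the list itself were not left out of these draws, with or without exon length matched. The percentile describes these libraries and is not a p-value. Lists with fewer than 5 measured members have no median. The rule names, per comparison, the 10 largest ratios in each direction at a mean of at least 5 CPM among genes with a name of their own (replication-dependent histones and mitochondrially encoded genes left out), 4 members per list and 14 fixed genes. In the list part, the largest ratio took the place of the smallest p-value, since no p-values exist. Genes with a mean of at least 50 CPM, random lists matched on exon length and counts without scaling beyond library size were added after the values were seen.

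The procedure was tested on simulated data, with counts drawn from the real means and depths and 200 genes changed. For S against G1, with 8320 genes at the minimum, 0% of genes changed 1.5-fold and 100% of those changed 2.5-fold or 4-fold were called, and 0 unchanged genes were called. The same shares held for G2/M against S over 8341 genes and for G2/M against G1 over 8393 genes. These simulated counts held counting noise only. For S against G1, unchanged simulated genes at 20 to 50 CPM had an SD of 0.061 on the log2 scale. The real libraries had a robust SD of 0.74 at that level. The simulation therefore does not show how often scatter between libraries alone passes 2-fold. Of 200 simulated unchanged lists, 5% fell outside the 95% range, and 90% of lists shifted by 0.5 on the log2 scale lay above it. Genes in this simulation varied independently and members were picked at random, so the 5% follows from the way it was built. It is not the rate for real lists, whose genes can vary together. Alternatives were relative log expression and upper-quartile factors, no scaling, leaving out histone, mitochondrial and ribosomal RNA genes, other filters on low counts, and leaving out each column in turn. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.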

Results

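C2C12 is a line of mouse myoblasts, muscle precursor cells that divide in rich medium and fuse into myotubes when serum is withdrawn. The series asks how chromatin in these cells relates to binding of the muscle transcription factor MyoD, and its 30 samples come from cells in the growing state, kept in 20% serum. Cells were stained with the DNA dye Hoechst for 15 minutes and sorted by DNA content into G1, S and G2/M fractions, per the labels' protocols. RNA-seq gave 6 columns of counts, 2 for each of the 3 phases, and the 24 ChIP-seq samples of 5 histone marks and their inputs are not analysed here. The question the RNA counts answer is which genes differ in RNA level between the phases of growing myoblasts.

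Each column held between 16109055 and 18103769 fragments assigned to genes. The labels number the 2 columns of a phase as replicates, without saying that they came from separate cultures. They differed by about as much as counting noise alone gives: chi-square over its degrees of freedom was 1.00 for G1, 1.03 for S and 1.15 for G2/M, where a value of 4.62 came from simulated replicates varying by 5%. One unnamed gene model, Gm17082, with 1920 fragments in one G2/M column and 258 in the other, carried most of the excess in G2/M, which was 1.04 without it. The 2 columns were therefore summed and counted as 1 library per phase, of 32395232 fragments in G1, 35822319 in S and 35907974 in G2/M. Counted so, there are no biological replicates, no difference between phases has a replicate check, and all intervals below are 95% intervals that cover counting error only. Of 46078 genes in the table, 14707 had a fragment in some library, and a count of 0 allows a level of up to 0.0937 CPM (counts scaled to library size) in G1, 0.0838 CPM in S and 0.0826 CPM in G2/M.

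The S library carried more RNA of mitotic genes and less RNA of DNA synthesis genes than the G1 library. Cenpf, a kinetochore protein, stood at 369.7 CPM in S and 42.4 CPM in G1, which is 8.72-fold higher in S, with a log2 ratio of 3.12 and a counting interval of 3.04 to 3.21. Kif11, the motor that pushes spindle poles apart, was 5.89-fold higher, and Cenpe, a kinetochore motor, 5.06-fold higher. In the other direction, Cdc6, which loads the replicative helicase at origins, was 12.5-fold lower in S, at 11.2 CPM against 140.5 CPM, with a log2 ratio of -3.64 and an interval of -3.80 to -3.50. Ccne2, an S-phase entry cyclin, was 5.15-fold lower and Pcna, the sliding clamp of DNA polymerases, 2.23-fold lower. Among the 500 genes of nearest mean level, 100% deviated less than Cenpf and 100% less than Cdc6.

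In GRCm38, Cenpf (ENSMUSG00000026605) lies on chromosome 1 from 189640606 to 189688086, and Cdc6 (ENSMUSG00000017499) lies on chromosome 11 from 98907801 to 98923940. Of the 8773 genes that reached 10 CPM in at least 1 of the S and G1 libraries, 757 were at least 2-fold higher in S and 755 at least 2-fold lower, together 17.2%. Most of these were genes of low level, where ratios spread widely. Among the 4228 genes with a mean of at least 50 CPM, a minimum chosen after the values were seen, 129 were at least 2-fold higher in S and 91 at least 2-fold lower, or 5.20%. The titles of the S columns carry a lot mark that the G1 and G2/M titles lack, so lot and phase cannot be told apart in either comparison with S. The robust SD of the log2 ratio was 1.16 at 5 to 20 CPM and 0.32 above 500 CPM.

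Genes were then described by lists fixed before the data were examined. Of the 56 measured genes of the G2/M and mitosis list, 50 were higher in S than in G1, 24 of them at least 2-fold, and none was 2-fold lower. The list's median log2 ratio of 0.83 lay above all 10000 random lists of like level (percentile 100). Ccnb1, the cyclin of mitotic entry, on chromosome 13 from 100778650 to 100786570, was 3.26-fold higher, with an interval of 1.64 to 1.77 around a log2 ratio of 1.71. Its partner Cdk1 was 1.79-fold higher and the proliferation antigen Mki67 2.27-fold higher. The importin Kpna2, which is not in this list and was picked after the values were seen, stood at 590.6 CPM against 145.1 CPM.

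The list of G1/S transition and DNA synthesis genes lay on the other side. Of its 42 measured members 32 were lower in S, 12 of them at least 2-fold, none was 2-fold higher, and the median of -0.71 lay below all random lists (percentile 0). Dtl, a substrate receptor of the ubiquitin ligase that clears licensing factors, was 5.88-fold lower, Cdca7, a chromatin-associated E2F and Myc target, 5.92-fold lower, and Wdr76 2.84-fold lower. Origin licensing and firing genes had a median of -0.38 (percentile 0.21), with 4 of 26 members at least 2-fold lower, among them the helicase subunit Mcm3 at 2.65-fold and the licensing factor Cdt1 at 3.83-fold. Several licensing genes, such as Cdc6 and Cdc45, are also in the G1/S list, so the medians of these lists are not separate results. The list of cyclins, their kinases and inhibitors, E2F and pocket proteins split, with 6 of 33 members 2-fold higher and 7 2-fold lower around a median of 0.12 (percentile 84.5). Within it, Ccna2, the cyclin of S phase and G2, was 2.40-fold higher and Ccnf, a cyclin-like ubiquitin ligase subunit, 6.10-fold higher, while Ccne1 was 3.09-fold lower and the kinase inhibitor gene Cdkn1a 2.27-fold lower.

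**Figure D1:**
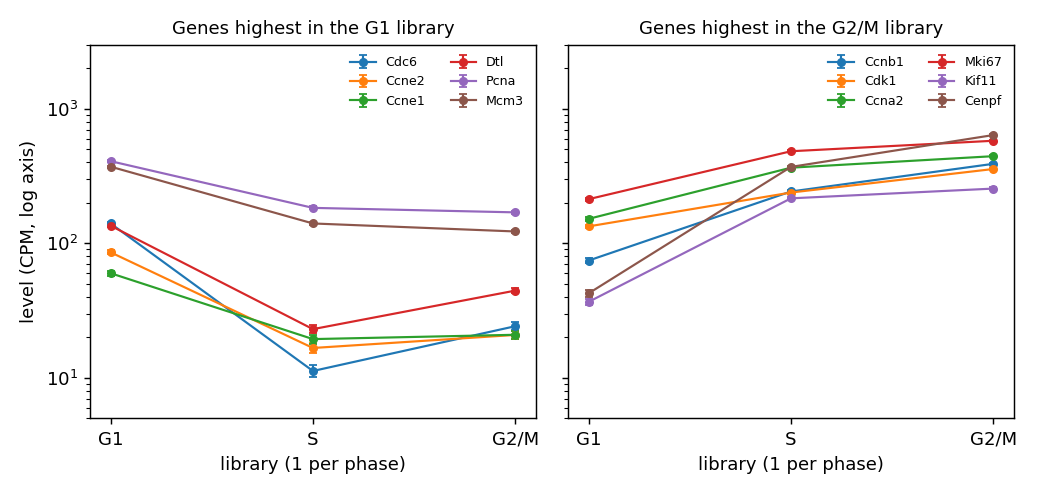
Level of 12 cell-cycle genes in the G1, S and G2/M libraries, in CPM on a log axis, with 1 summed library per phase and 95% intervals that cover counting error only. Ccnb1 stands at 74.4, 242.7 and 389.8 CPM in G1, S and G2/M, and Cdc6 at 140.5, 11.2 and 24.2 CPM.

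Ribosomal and mitochondrial genes also differed between these libraries. All 82 measured genes of cytosolic ribosomal proteins were lower in S than in G1, with a median of -0.40 (percentile 0), as in Rpl37a at 143.2 CPM against 337.1 CPM. Fragments of near-identical copies can be split by the counting, so single members such as Rps3a3, at 89.7 against 196.2 CPM, are uncertain. Of 10 measured mitochondrially encoded genes 8 were lower in S, with a median of -0.38 (percentile 0.54), as in mt-Cytb at 2647 CPM against 3659 CPM. Shorter genes were lower in S as a class, with a median of -0.22 among genes of up to 2606 exon bases and 0.27 among genes of more than 7856 exon bases, at a mean of at least 50 CPM. Against random lists matched on exon length as well, the ribosomal proteins kept percentile 0, while the mitochondrial list stood at 18.7. Ribosomal protein genes, all lower in S, were not left out of these draws. The value of 18.7 therefore does not show that length accounts for the mitochondrial difference.

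Muscle regulators differed little as a group between S and G1. The 22 measured myogenic regulators had a median of 0.08 (percentile 69.4). Myf5, the myoblast determination factor, on chromosome 10 from 107482908 to 107486134, was 1.91-fold higher in S, at 126.2 CPM against 66.0 CPM, and the homeobox factor Six4 2.09-fold higher. Myod1 was low in all libraries, with 218 fragments in S and 213 in G1, a log2 ratio of -0.13 whose interval of -0.41 to 0.15 includes 0. Myog, the differentiation factor, had 80 fragments in G1 and 0 in S, which makes it at least 29.8-fold lower in S, at a level under the 10 CPM minimum. At a mean of 1 to 5 CPM, 78.5% of genes differed at least 2-fold between S and G1, with a robust SD of 4.75, so such ratios are common there. Pax7, the satellite cell factor, had 0 fragments in both. Of the 37 sarcomere genes only 4 reached the minimum, too few for a median: Tnnc1 was 6.68-fold lower in S, Actn3 had 0 fragments against 350, Ldb3 stood at 17.9 against 28.0 CPM and Tnnt2 at 96.7 against 103.2 CPM.

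The remaining lists lay inside the middle 95% of random lists between S and G1. Their medians were 0.02 for histone variants and chaperones (percentile 62.6), 0.08 for immediate early genes (76.1), 0.00 for H3K4 and H3K27 modifiers (52.4), -0.17 for heat shock genes (23.3), 0.06 for p53 targets (67.4), -0.09 for cholesterol synthesis (20.5), 0.07 for extracellular matrix genes (90.7) and -0.27 for the Notch pathway (17.4). Among their members, Cenpa, the centromeric histone, was 2.06-fold higher, the AP-1 subunit Junb 2.97-fold lower, the deacetylase Hdac1 1.62-fold lower and the Notch ligand Jag2 3.05-fold lower. These deviations exceeded those of 92.0%, 94.6%, 91.6% and 96.6% of like-level genes, in that order, and that of Ezh2, the H3K27 methyltransferase, 1.36-fold lower, exceeded 74.0%. Malat1, a nuclear-retained RNA, was 3.07-fold higher in S while Neat1, another, stood at 196.2 against 193.5 CPM; only these 2 of 7 nuclear-retained and ribosomal RNA genes were measured. Replication-dependent histones, most of whose RNAs lack a poly(A) tail, had 1 measured gene of 64, Hist1h1c, at 71.8 CPM in S and 101.2 CPM in G1. Of 30 markers of other cell types, 4 reached the minimum: Krt14 at 285.4 against 325.9 CPM, Runx2 at 103.5 against 65.2 CPM, Sox9 at 39.4 against 34.2 CPM and Pparg at 14.4 against 43.6 CPM.

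By the rule fixed for named genes, the largest ratios belonged to genes that reached only 10.02 to 24.2 CPM in the higher library. Higher in S were Sytl5, with 866 fragments against 6, Aste1 with 661 against 7, and Arhgef39 and Ank3, at least 162-fold and at least 147-fold above a count of 0 in G1. Lower in S were Coq4, a factor of coenzyme Q synthesis, with 5 fragments against 501, and the lysosomal enzyme Idua and the ADP-ribosyltransferase Parp10, at least 142-fold and at least 158-fold below G1. Sapcd2, with 569 fragments in S, had 3 in G1, and Atxn7l2 had 1 fragment in S and 573 in G1. At a mean of at least 50 CPM, in a selection made after the values were seen, the chromosomal passenger Incenp was 4.19-fold higher in S, the spindle protein Nusap1 3.97-fold higher, and the single-strand DNA binding subunit Rpa2 2.92-fold and the checkpoint kinase Chek1 2.84-fold lower.

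Between the S and G2/M libraries the mitotic genes went further in the same direction, while the DNA synthesis genes differed in both directions around a median near 0. Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, was 2.64-fold higher in G2/M than in S, at 108.0 CPM against 40.9 CPM, with a log2 ratio of 1.40 and an interval of 1.31 to 1.49. Ccnb1 was 1.61-fold higher (log2 ratio 0.68, interval 0.65 to 0.72), Cdk1 stood at 356.7 against 238.4 CPM, and Cks2, a small subunit of the mitotic kinase, was 2.65-fold higher. Immediate early genes were lower in G2/M, among them Egr1, a serum-response transcription factor, at 27.4 CPM against 95.1 CPM, which is 3.47-fold lower with an interval of -1.90 to -1.69 around -1.79. Insig1, a sensor of sterols, was 1.64-fold lower.

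Of 8751 genes that reached 10 CPM in S or G2/M, 620 were at least 2-fold higher in G2/M and 581 at least 2-fold lower, together 13.7%, fewer than between S and G1. With a mean of at least 50 CPM the counts were 40 and 60 of 4212 genes. Egr1 lies on chromosome 18 from 34859823 to 34864984.

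In the G2/M and mitosis list, 52 of 57 measured genes were higher in G2/M than in S, 9 of them at least 2-fold and none 2-fold lower, with a median of 0.58 (percentile 100). Plk1, a kinase of mitotic entry and exit, stood at 204.5 CPM against 96.8 CPM, and Cdc20, the activator of the anaphase-promoting complex, at 205 CPM against 90.0 CPM. Ccnb2 was 2.55-fold higher. Cyclins, kinases and E2F genes had a median of 0.34 (percentile 99.9), with 2 of 32 members 2-fold higher, one of them the pocket protein Rbl2 at 3.01-fold, and the phosphatase Cdc25b 1.79-fold higher. Ccna2 differed by 1.22-fold, Mki67 stood at 578.5 against 483.4 CPM, and Ccnd1, the cyclin of growth factor signalling, stood at 725.5 against 693.7 CPM.

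DNA synthesis genes had a median of -0.11 (percentile 10.7) between S and G2/M, with 4 of 41 members 2-fold higher and 5 2-fold lower in G2/M. Pcna stood at 169.8 CPM in G2/M and 183.3 CPM in S, and Ccne1 at 20.9 against 19.4 CPM. The repair glycosylase Ung was 10.7-fold lower in G2/M, with 46 fragments against 484, and the nucleosome assembly factor Chaf1b 3.21-fold lower, whereas the exonuclease Exo1 was 2.89-fold higher. Licensing genes had a median of -0.13 (percentile 10.3), or -0.44 at a mean of at least 50 CPM, with 3 of the 26 2-fold higher and 3 2-fold lower; Gins3 was 2.60-fold lower and Cdc45 2.57-fold higher, both parts of the replicative helicase.

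Immediate early genes had a median of -0.60 (percentile 0) and 19 of 21 measured members were lower in G2/M than in S, 3 of them at least 2-fold, as in the mRNA decay factor Zfp36, 3.57-fold lower. Junb went the other way, 2.96-fold higher. Cholesterol synthesis genes had a median of -0.28 (percentile 0.62), with 17 of 21 lower, among them the reductase Dhcr7 at 2.30-fold. The p53 target list had a median of -0.40 (percentile 0.66), or -0.22 at a mean of at least 50 CPM, with Zmat3 2.27-fold lower and Sesn2 3.05-fold lower, while Cdkn1a stood at 22.5 against 20.6 CPM. Ribosomal protein genes were higher in G2/M than in S, 63 of 80 with a median of 0.24 (percentile 100), as in Rps2 at 224.6 against 116.8 CPM. All 10 mitochondrially encoded genes were lower, with a median of -0.32 (percentile 0.34), as in mt-Co1 at 4066 against 5468 CPM.

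The other lists stayed inside the middle 95% of random lists. Medians between G2/M and S were 0.04 for histone variants and chaperones (percentile 66.5), -0.08 for myogenic regulators (25.9), 0.04 for H3K4 and H3K27 modifiers (64.1), 0.14 for heat shock genes (89.4), -0.10 for extracellular matrix genes (17.7) and 0.21 for the Notch pathway (79.3). Myf5 stood at 127.7 against 126.2 CPM, a log2 ratio of 0.02 with an interval of -0.04 to 0.08, and Myod1 had 208 fragments against 218. Pax7 had 119 fragments in G2/M and 0 in S, and Myog 42 against 0. At a mean of 1 to 5 CPM, 75.4% of genes differed at least 2-fold between G2/M and S. Jarid2, an accessory subunit of Polycomb repressive complex PRC2, was 2.96-fold higher in G2/M, the H3K4 demethylase Kdm5b 4.41-fold higher, and Ezh2 1.39-fold higher. The histone variant H2afz was 1.54-fold higher and the chaperone Hspa8 1.56-fold higher. Neat1 was 2.00-fold lower and Malat1 1.37-fold lower, the 2 measured genes of their list. Histone genes (Hist3h2a and Hist1h1c, 2 measured), sarcomere genes (3 measured) and markers of other cell types (4 measured) were too few for a median; Hist1h1c stood at 99.4 against 71.8 CPM, Tnnt2 at 97.0 against 96.7 CPM and Krt14 at 232.3 against 285.4 CPM.

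The largest ratios by the rule again came from genes that reached only 10.1 to 24.4 CPM in the higher library. Higher in G2/M were the metallothionein Mt2, with 885 fragments against 21, Xdh, xanthine dehydrogenase, with 663 against 11, and Cped1 with 640 against 5, and the corepressor Tle4 had 373 against 0. Lower in G2/M were the recombination factor Rad51d, with 12 fragments against 490, the sorting nexin Snx10 with 8 against 599, the helicase Dhx35 with 5 against 590, and Zdhhc1 with 1 against 610. With a mean of at least 50 CPM, again a selection made after the values were seen, Emp3 was 3.03-fold and the von Hippel-Lindau gene Vhl 2.63-fold higher in G2/M, and the actin nucleation subunit Arpc5l was 3.28-fold, the repair gene Brca1 2.91-fold and the deoxycytidine kinase Dck 2.77-fold lower.

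G2/M against G1 gave the widest differences of the 3 comparisons. Cenpf was 15.0-fold higher in G2/M (log2 ratio 3.91, interval 3.83 to 3.99), the mitotic kinesin Kif14 13.8-fold, the spindle pole protein Aspm 7.91-fold and Ccnb1 5.24-fold higher. Ung was 54.3-fold lower, with 46 fragments against 2205, Cdc6 5.81-fold lower (log2 ratio -2.54, interval -2.64 to -2.43) and Chaf1b 5.72-fold lower. Kif14 and Aspm were singled out by the 50 CPM minimum after the values were seen, as was Chaf1b, which the fixed G1/S and chaperone lists also hold.

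Of 8848 genes that reached 10 CPM in G1 or G2/M, 883 were at least 2-fold higher in G2/M and 872 at least 2-fold lower, together 19.8%. With a mean of at least 50 CPM the counts were 160 and 118 of 4222 genes. Across all 3 phases, 2859 of 9070 genes differed at least 2-fold between some pair of libraries, with the highest level in G1 for 1099, in S for 772 and in G2/M for 988. Pearson's r of log2 CPM, across genes that are not independent replicates, was 0.880 for S and G1, 0.902 for G2/M and S, and 0.857 for G2/M and G1.

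Of 57 measured G2/M and mitosis genes 54 were higher in G2/M than in G1, 39 of them at least 2-fold and none 2-fold lower, with a median of 1.35 (percentile 100). Top2a, the topoisomerase that untangles sister chromatids, stood at 1499 against 376.1 CPM, and Cenpa was 2.92-fold higher. Kpna2, which is not in this list, stood at 1097 against 145.1 CPM. Cyclins, kinases and E2F genes had a median of 0.26 (percentile 98.2), with 11 of 33 at least 2-fold higher and 7 at least 2-fold lower. At a mean of at least 50 CPM their median was 0.22 (percentile 95.05), inside the 95% limits. Ccna2 was 2.93-fold higher, Cdk1 2.67-fold higher and Ccne1 2.87-fold lower. In the G1/S list 37 of 42 genes were lower in G2/M, 16 of them at least 2-fold and 1 at least 2-fold higher, with a median of -0.72 (percentile 0). Pcna was 2.40-fold lower, and Ccne2 4.12-fold lower. Licensing genes had a median of -0.57 (percentile 0), or -1.05 at a mean of at least 50 CPM, with 9 of 26 at least 2-fold lower and none 2-fold higher, as in Mcm3, 3.03-fold lower.

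**Figure D2:**
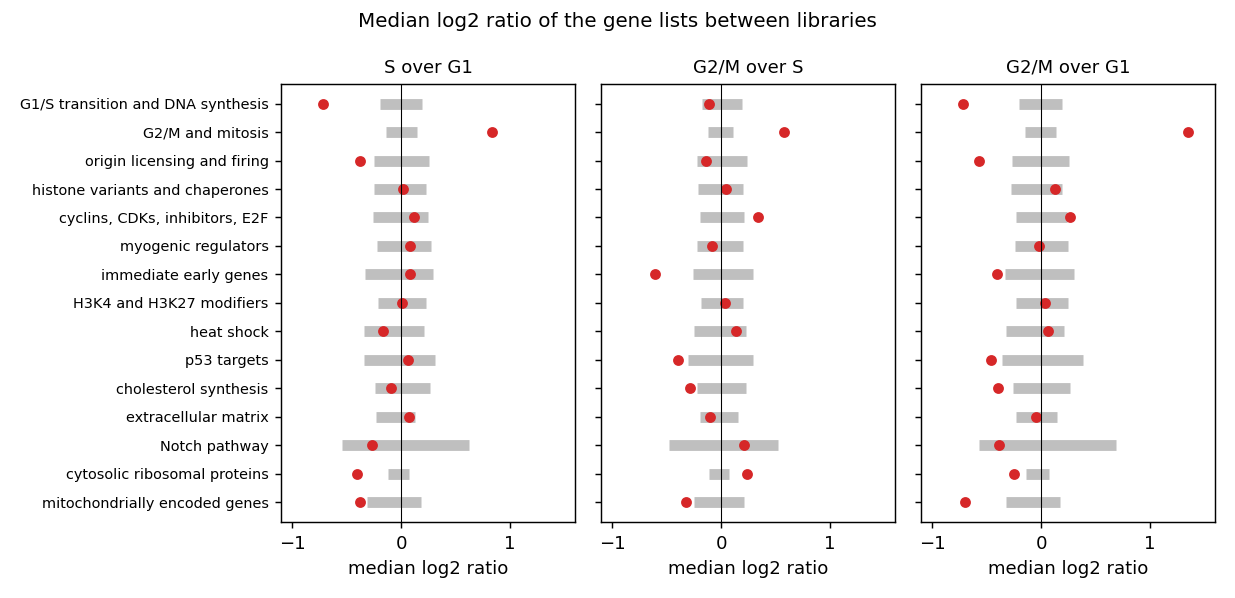
Median log2 ratio of each gene list (red points) in the 3 comparisons, with the range that holds 95% of 10000 random lists of like level (grey bars). The G2/M and mitosis list stands at 0.83, 0.58 and 1.35, to the right of its random lists each time, and myogenic regulators at 0.08, -0.08 and -0.02, inside theirs.

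Ribosomal protein genes were lower in G2/M than in G1, 67 of 82 with a median of -0.24 (percentile 0), and 9 of 10 mitochondrially encoded genes were lower, with a median of -0.69 (percentile 0), as in mt-Co1 at 4066 against 7272 CPM. Cholesterol synthesis genes had a median of -0.40 (percentile 0.15), with 15 of 20 lower and the cyclase Lss 1.78-fold lower. Immediate early genes had a median of -0.40 (percentile 0.86), or -0.089 at a mean of at least 50 CPM, with 14 of 19 lower; Egr1 was 2.63-fold lower and the AP-1 subunit Fosl1 3.58-fold higher. Matched on exon length as well, this list stood at percentile 3.08. The p53 targets had a median of -0.46 (percentile 0.77), with Cdkn1a 2.08-fold lower, but their median was -0.04 (percentile 37.8) among members with a mean of at least 50 CPM.

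Muscle and chromatin genes showed single differences without a shift of their lists between G2/M and G1. Medians were -0.02 for myogenic regulators (percentile 46.9), 0.03 for H3K4 and H3K27 modifiers (57.0), 0.12 for histone variants and chaperones (91.1), 0.07 for heat shock genes (82.5), -0.05 for extracellular matrix genes (55.3) and -0.39 for the Notch pathway (8.07). Myf5 was 1.93-fold higher in G2/M, with an interval of 0.88 to 1.03 around a log2 ratio of 0.95, and the muscle transcription factor Mef2a 2.27-fold higher. Myod1 stood at 5.73 against 6.65 CPM, with an interval of -0.50 to 0.07, and Myog had 42 fragments against 80. Pax7 had 119 fragments in G2/M, at least 35.0-fold above its count of 0 in G1 but at only 3.28 CPM. At a mean of 1 to 5 CPM, 82.9% of genes differed at least 2-fold between G2/M and G1, with a robust SD of 6.56 on the log2 scale. Jarid2 was 5.03-fold higher, the H3K27 demethylase Kdm6b 2.27-fold higher, and Ezh2 stood at 205.6 against 201.1 CPM. Notch2 was 2.13-fold lower and its ligand Jag1 3.25-fold lower. Among lists with too few measured genes for a median, Malat1 was 2.23-fold higher and Neat1 1.98-fold lower, Tnnc1 had 60 fragments against 580 and Tnnt2 stood at 97.0 against 103.2 CPM, Hist1h1c stood at 99.4 against 101.2 CPM, and Krt14 stood at 232.3 against 325.9 CPM.

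The largest ratios by the rule included Fam83d, a spindle protein, with 2211 fragments in G2/M against 14 in G1, or 139-fold, the only one of these genes above 20 CPM in either library. Xdh was at least 195-fold and Akap17b at least 170-fold above a count of 0 in G1, and Ifi203, an interferon-induced gene, was at least 215-fold and the ephrin Efnb3 at least 131-fold lower in G2/M. Wnt4, a secreted signalling protein, had 1 fragment in G2/M against 541 in G1, and Thap3 had 2 against 441.

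**Figure D3:**
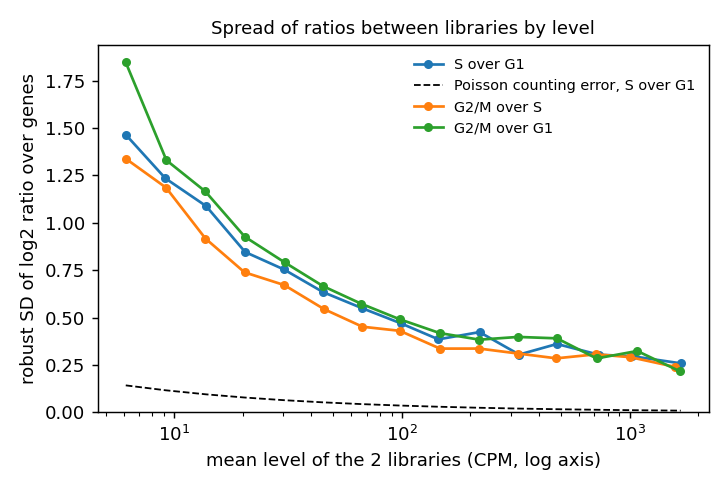
Robust SD of the log2 ratio of genes in bins of mean level, in CPM on a log axis, for the 3 comparisons. A dashed line gives the SD from counting error alone between S and G1. Over wider ranges than the bins drawn, the SD between S and G1 was 1.16 at 5 to 20 CPM and 0.32 above 500 CPM.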

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

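The counts of genes depended on the minimum level, and no ratio or list median changed sign among those called. With no filter on low counts, 2409 genes were at least 2-fold higher and 2001 lower in S than in G1, 1791 higher and 2245 lower in G2/M than in S, and 2226 higher and 2293 lower in G2/M than in G1. Then 6688 genes differed between some phases, 2364 of them highest in G1, 2182 in S and 2142 in G2/M. With 1 CPM required in at least 2 libraries the pairwise counts were 1333 and 1186, 1050 and 1110, and 1443 and 1428, in the same order, and the other 4 counts stayed within 1.5 times. At a mean of at least 50 CPM, chosen after the data were seen, they were 129 and 91, 40 and 60, and 160 and 118; 441 genes differed between some phases, 154 highest in G1, 126 in S and 161 in G2/M. These counts follow from how many low-level genes are counted. At this minimum the licensing genes had a median of -0.44 for G2/M against S (percentile 0.05, outside the 95% limits only here) and -1.05 for G2/M against G1. With fewer members, p53 targets moved inside the limits in G2/M against S (-0.40 to -0.22, percentile 11.8) and against G1 (-0.46 to -0.039, 37.8), as did immediate early genes (-0.40 to -0.089, 30.3) and cyclins, kinases and E2F genes (0.26 to 0.22) in G2/M against G1; the cause was not tested. Among random lists matched also on exon length, 43 of 45 list medians stayed on their side of the 95% limits; mitochondrially encoded genes in S against G1 moved to percentile 18.7 and immediate early genes in G2/M against G1 to 3.08. Under relative log expression, upper-quartile factors, no scaling (chosen after the data were seen) and leaving out histone, mitochondrial and ribosomal RNA genes, all 10 counts stayed within 1.5 times, list medians moved by less than the range of random lists, and named ratios stayed within their counting intervals or within 0.05. Of 45 list comparisons, which are not independent because several lists share genes, 21 lay outside the 95% limits. The same 21 did under the 3 other scalings and without each column, and all 18 of them that could be tested did with histone, mitochondrial and ribosomal RNA genes left out. With no filter, as low-level members entered, 4 of the 21 moved inside: mitochondrially encoded genes in S against G1 (median from -0.38 to -0.22, percentile 8.72) and in G2/M against S (-0.32 in both, 3.85), p53 targets in G2/M against S (-0.40 to -0.31) and immediate early genes in G2/M against G1 (-0.40 to -0.31, 2.80). The last also did with 1 CPM in at least 2 libraries (-0.22, 9.62). Percentiles under these alternatives came from fewer random lists than the main results, so 2.80 and 3.08 lie too close to the limit to be sure. Without each column in turn, genes higher in S than in G1 ranged from 744 to 769, and 9 to 17 of 342 named ratios moved beyond their counting intervals. No named ratio of at least 2-fold changed sign, and smaller ratios were not checked for this. No paired analysis was possible because each phase was counted as 1 library, and for the same reason DESeq2, limma-voom, an FDR of 0.01, glmTreat at 1.5-fold, the fit of 4 libraries, the replicate block, camera with an estimated correlation and fry were not run. Depth limits single genes mainly near the floor of 3 fragments.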

Other observations

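The gene families, the 50 CPM minimum and 7 of the 9 tests below were chosen after the values were seen: those of exchanged labels, of a mixture (2), of transcript length (2), of late G1 cells in the G1 gate and of uneven amplification. All 9 tests address patterns first seen in these values, and none was among the tests planned before the data were examined. Of 29 measured kinesins, motors that include the spindle motors, 11 were at least 2-fold higher in S than in G1 and none 2-fold lower; 4 are also in the fixed mitosis list. Between G2/M and G1 the median of 27 was 0.84 (percentile 100, also with exon length matched), with 13 at least 2-fold higher and 3 2-fold lower, and between G2/M and S it stayed inside the 95% limits (percentile 92.1), with 2 of 28 2-fold higher and 4 2-fold lower. Kif14 stood at 9.83 CPM in G1, 72.3 CPM in S and 135.2 CPM in G2/M. Condensin and cohesin subunits, which compact and hold chromatids, were higher in S than in G1 for 12 of 13 members, with a median of 0.71 (percentile 100); Smc4, one of 2 that the fixed lists also hold, stood at 302.4, 635.5 and 788.4 CPM in G1, S and G2/M, and Ncapd3 was the exception at 39.7, 21.4 and 25.8 CPM. Genes named as centromere proteins had a median of 0.10 between S and G1 (percentile 73.6) and of 0.62 between G2/M and G1 (percentile 99.8 with exon length matched), where 8 of 18 were at least 2-fold higher and 5 at least 2-fold lower.

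Collagens were lower in G2/M than in S for 12 of 15 members, with a median of -0.38 (percentile 0.465 with exon length matched), as in Col5a1 at 455.4 against 660.9 CPM; 7 of them are in the fixed list of extracellular matrix genes, whose median of -0.10 lay inside its random range. Integrins, adhesion receptors, had a median of -0.37 (percentile 1.35 with exon length matched), with 8 of 9 lower, as in Itgb5 at 60.5 against 94.6 CPM. Tubulins had a median of 0.29 in the same comparison (percentile 99.3), but percentile 90.5 with exon length matched. Nuclear-encoded subunits of the respiratory chain and ATP synthase had a median of -0.33 between S and G1 (percentile 0), but 3.82 with exon length matched, and proteasome subunits -0.21 (0.47, then 30.2). Ribosomal protein genes were not left out of the length-matched draws, so these values do not show that length accounts for either difference. Splicing factors of the SR family and translation initiation factors stayed inside the middle 95% of random lists in all 3 comparisons. A level in S alone of at least 1.5 times both other libraries, at a mean of at least 50 CPM, was seen for 84 of 4181 genes, among them the transcription factor Runx1 at 52.3, 115.4 and 53.9 CPM in G1, S and G2/M. A level as far below both was seen for 93, among them the elastic fibre protein Efemp2 at 78.8, 26.2 and 72.5 CPM. The median exon length was 5819 bases for the 84 genes, 3096 for the 93 and 4601 for all, so both groups go with the length trend of the S library.

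Genes of the G1/S list were lower in the S library than in the G1 library, with a median of -0.71. Exchanged labels of the 2 libraries would put mitotic genes lower in S, and their median was 0.83, while a trend with transcript length is set against by percentile 0 among lists matched on length, whose medians ranged from -0.16 to 0.20. An S library that is a mixture of G1 and G2/M cells stays open. At the 53.3% of G2/M that best matched mitotic genes, a mixture predicts a median of -0.34. Members lay a median of -0.21 from their predicted level, 27 of 42 below it, with a bootstrap interval of -0.58 to 0.005. The bootstrap resampled genes of the mitotic and G1/S lists as if independent, so it does not measure spread between libraries. Among random lists of like level the median of -0.21 stood at percentile 0.42, and at 0.19 with exon length matched as well. Of the 42, 7 were at least 1.5-fold lower in S than in both other libraries, which a mixture alone does not give, as in Cdc6, against 0 to 5 in random lists, but the 11 at 1.2-fold and the 14 at any size were within the 2 to 11 and 7 to 19 of random lists, so these sizes disagree. Late G1 and early S cells inside the G1 gate cannot be told apart from a true peak in G1. The test asked whether replication-dependent histone genes were highest in S, which both would give, and only 1 such gene was measured. A rise of G1/S genes before S phase, the biological explanation that the sort allows, may therefore hold but stays untested. The lot marked in the S titles is untested too.

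Ribosomal protein genes were lower in the S library than in the G1 library, with a median of -0.40. Lists matched on length had medians from -0.32 to -0.13, and the ribosomal list stood below all of them (percentile 0). Part of the difference may follow the trend with transcript length. The matched lists cannot measure that part, since ribosomal genes themselves could be drawn into them. A few genes taking most of the counts would shift other shares by more than was seen, as the share outside the 10 most abundant genes differed by 0.0077 on the log2 scale. The summed level of the 82 genes was 42355 CPM in G1, 31555 CPM in S and 35989 CPM in G2/M. The lot of the S library, marked in its title alone, cannot be told apart from its phase, and no biological explanation was tested.

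Ratios spread widely at low levels, with a robust SD of 0.74 at 20 to 50 CPM between S and G1. If few RNA molecules had been sampled per library, at 0.329 molecules per CPM as the spread would need, 225 genes at 5 to 10 CPM would be at the floor in 1 library, and 17 were, a ratio of 0.0755. With molecules fitted instead to absent genes at 2 to 5 CPM, 23.2 genes were predicted against the same 17, a ratio of 0.73. The ratio was 0.59 for G2/M and S and 0.75 for G2/M and G1. This fit predicts absent genes only and models neither amplification nor the spread. A small number of RNA molecules, unevenly amplified, may therefore account for the spread, but the fit cannot decide it. Cell-cycle differences among low-level genes remain possible and were not tested apart from this spread.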
